A study of Mus musculus with 2 samples.

How the data were processed

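The series holds 2 samples, each 1 Affymetrix mouse 3′ expression array hybridised with labelled RNA from a primary keratinocyte culture. Per the labels' protocols, epidermis of newborn mice was separated with dispase and trypsin, keratinocytes were grown on collagen-coated dishes, and biotin-labelled cRNA was made from total RNA with an oligo-dT primer. The groups, control and labelled MED1-null, were taken from the genotype given in the labels. Each group has 1 array, so no replicates were averaged and no samples were left out.

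The values used were those the authors deposited: 1 signal intensity per probe set on a linear scale, made by MAS5 in Affymetrix GeneChip Operating Software, per the submitters' processing notes and the design text. A probe set is a group of short probes for a transcript, mostly near its 3′ end, summarised as a single signal. The software version was not given in the sources used here, and detection calls were not used here. From the values, each array had been scaled as a whole to a mean of 500 after trimming 2% of probe sets at each end. The median of probe sets other than controls was 64.1 on the control array and 71.4 on the array labelled MED1-null. MAS5 subtracts mismatch signal, which leaves low values noisy. For this reason values under the median of all non-control probe sets pooled over both arrays, 67.7, were raised to that floor before log2 was taken. A gene at the floor on 1 array has only a bound, written as "at least" N-fold, and a gene below the floor on both arrays counts as not measured.

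Of 45101 probe sets, 64 are Affymetrix controls. Gene symbols came from GEO's platform annotation: 34945 probe sets had 1 symbol, 932 several and 9160 none, and 34741 were found by Entrez ID in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table was used for names and chromosomes only. No gene was named from a probe set with several symbols. Probe sets with several symbols or none were left out of gene counts, and among them 69 were at least 2-fold higher and 30 at least 2-fold lower on the array labelled MED1-null. For each of 18193 genes, the probe set with the highest mean signal over both arrays was used. The floored log2 signal of the control array was subtracted from that of the array labelled MED1-null, and genes with a ratio of 2 or more in either direction were counted.

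With 1 array per group no test between groups was possible. The spread between probe sets was computed as the pooled within-gene SD of the log2 ratio over 4916 genes with several probe sets at the floor on both arrays (13160 probe sets). It covers differences between probe sets, not between animals or cultures. Pearson's r between the arrays over the 20821 probe sets at the floor on both, which are not independent replicates, was 0.975. The median log2 ratio of these was 0.06, and 96.4% lay within 2-fold. The 18 hybridisation spike-in probe sets had log2 ratios from -0.17 to 0.21.

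The floor, the thresholds, 46 gene lists (31 of biology, 1 of general reference genes, 1 of X-inactivation and Y-linked genes, and 13 of cell type markers), the rule for named genes and the alternatives were chosen before the data were examined. For each list the members at the floor on either array were counted as at least 2-fold higher, at least 2-fold lower or between. Their median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean log2 signal in 20 bins. Percentiles 2.5 and 97.5 of the random medians bound the range drawn with each list. The percentile describes these arrays and is not a p-value. Genes were named from among Med1, the 12 with the highest and the 12 with the lowest ratio, and per list up to 4 members with the ratio farthest from 0 in either direction, or up to 2 where all members lay within 2-fold. The 12 per direction had to reach 4 times the floor on the higher array and to have all probe sets at the floor on either array in the same direction, and provisional symbols were left out. Where 5 or fewer members of a list were beyond 2-fold in a direction, those past the first 4 of the list were also named, after their values were seen.

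The counting and the list percentiles were tested on a simulated pair of arrays over 18193 genes, with the signal-dependent spread of the real pair and 200 genes changed. Of genes changed 3-fold, 96% were counted in each direction, and of genes changed 5-fold, 100%. Among the unchanged genes, 155 were counted as higher and 128 as lower. Of 200 simulated lists of unchanged genes, 93.5% fell between percentiles 2.5 and 97.5, and 100% of 50 lists shifted down by 0.5 fell below percentile 2.5. These lists were drawn at random and their noise was independent for each probe set. Genes that move together between cultures were not simulated, so the 93.5% does not cover lists of such genes.

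Alternatives were a floor at the 25th (18.1) or 75th percentile (434.6) or none, rescaling to a median ratio of 1, quantile normalization, a lowess curve with a span of 0.4, the mean over a gene's probe sets, and leaving out probe sets whose suffix marks shared sequence. Thresholds of 1.5-fold and 3-fold, counts of probe sets, genes with agreeing probe sets alone, list members at the floor on both arrays, and list means were also tried. Leaving out X and Y chromosome genes, and leaving the stress response genes out of the other lists, were added after the data were seen. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.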

Results

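Gene expression was measured in primary keratinocytes, the main cell type of the epidermis, grown from the skin of newborn C57BL/6 mice. One culture came from control mice, named MED1flox/flox in their title and wild-type in their source. The other came from mice carrying K5Cre, a Cre recombinase driven by the keratin 5 promoter, which were labelled keratinocyte-specific MED1 null. MED1 is a subunit of Mediator, the complex that links transcription factors, nuclear receptors among them, to RNA polymerase II. Each culture was hybridised to 1 Affymetrix array, so that the comparison rests on 2 arrays with no replicates. No test, p-value or spread between cultures could be computed, and the number of arrays limits the precision of each value. The spread that could be measured was that between probe sets of the same gene, with a pooled SD of 0.31 log2 units over 4916 genes, which corresponds to 1.24-fold. The 3′ over 5′ signal ratio of the Gapdh control probe sets was 0.762 on the control array and 0.767 on the array labelled MED1-null, and that of beta-actin was 1.13 and 1.14. The ratio of the transferrin receptor differed more, at 1.76 and 2.37.

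The targeted gene was examined first. Med1 signal was higher on the array labelled MED1-null than on the control array, against what the label would lead one to look for. The Med1 probe set with the highest signal read 462.7 on the control array and 1039 on the array labelled MED1-null, a 2.25-fold difference (log2 ratio 1.17). The other 3 that reached the floor on both arrays read 318.3 and 944.2, 93.2 and 228.5, and 139.7 and 205.0. All 7 Med1 probe sets were higher on the array labelled MED1-null, and 3 of them lay below the floor of 67.7, the median signal to which lower values were raised, on the control array. Over the 6 probe sets that reached the floor on either array, log2 ratios ran from 0.55 to 1.57. The labels do not give the deleted part of the gene, and the position of the probe sets along the transcript was not used here. A probe set outside the deleted part checks nothing about the deletion, so these values neither bear out nor refute the labels. For this reason the array is called the array labelled MED1-null throughout, and each direction below is that of the labels. Of 32 measured Mediator subunit genes, Med1 was the only one at least 2-fold apart between the arrays by the probe set used. The list had a median log2 ratio of 0.08 at percentile 60.1 of random lists matched on signal. Med26, at 346.4 and 229.0, came next in size, followed by Cdk8 (1.25-fold higher) and Med22 (1.23-fold lower). The probe sets of Med26 went both ways, with log2 ratios from -0.60 to 1.19.

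The arrays also differed in sex-linked transcripts. Xist, the RNA that coats the inactive X chromosome of female cells, read 5461 on the control array and 55.7, below the floor, on the array labelled MED1-null, at least 80.7-fold lower. The Y-linked genes Eif2s3y (4.2 against 2164), Kdm5d (1.5 against 380.9) and Uty (24.5 against 221.7) were below the floor on the control array and at least 32.0-fold, 5.63-fold and 3.27-fold higher on the array labelled MED1-null. Sex-linked transcripts therefore differed along with the genotype label in every comparison below. The 332 measured X-linked genes other than Xist had a median log2 ratio of -0.003, and the 11268 measured autosomal genes one of 0.06.

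**Figure D1:**
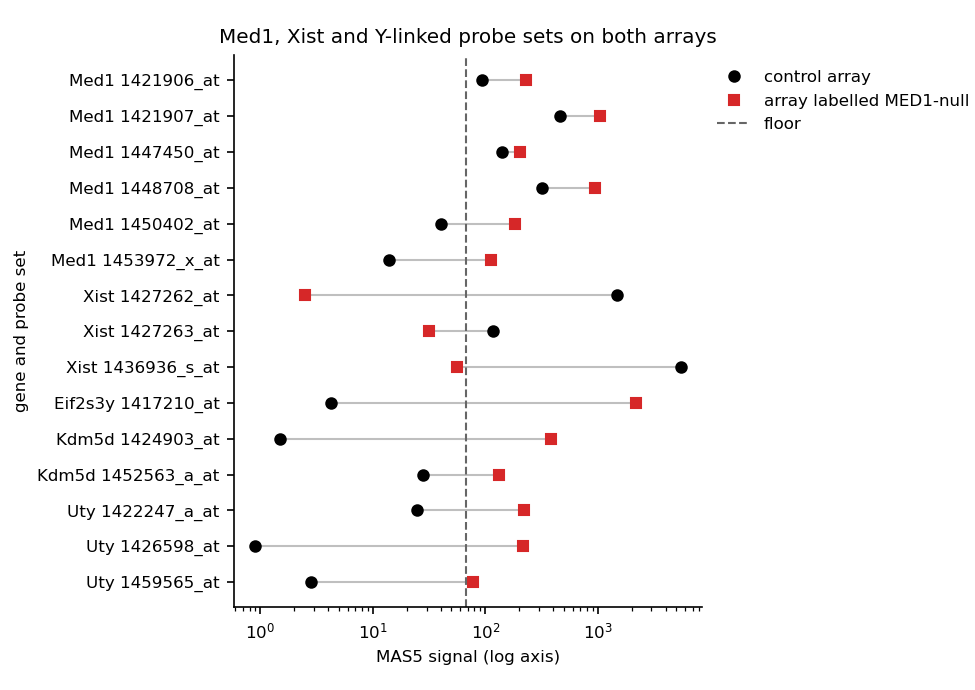
MAS5 signal on a log axis for each probe set of Med1, Xist, Eif2s3y, Kdm5d and Uty that reached the floor on either array, with the control array as circles, the array labelled MED1-null as squares and the floor of 67.7 as a dashed line. Every Med1 square lies to the right of its circle, Xist is high on the control array alone, and the Y-linked genes are high on the array labelled MED1-null alone.

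The comparison asked how gene expression in MED1-null keratinocytes differed from that in control keratinocytes. Of 11621 genes that reached the floor on either array, 190 were at least 2-fold higher and 259 at least 2-fold lower on the array labelled MED1-null, together 3.86% of the measured genes. Among genes with 4 times the floor on the higher array and probe sets in the same direction, the highest ratios outside the Y chromosome belonged to Igf2, an insulin-like growth factor (4.78-fold), Gjb2, the gap junction protein connexin 26 (4.52-fold), and Cdk20 (4.34-fold). They were followed by the antimicrobial peptide gene Defb1 (4.17-fold), Psapl1 (4.02-fold), the surface protein Cd109 (3.78-fold) and the vasodilator peptide gene Adm (3.68-fold). The matrix protein gene Tgfbi (3.57-fold), the growth factor Pdgfb (3.51-fold) and the clock transcription factor Arntl2 (3.34-fold) completed the group. The lowest ratios after Xist belonged to Slpi, a secreted inhibitor of leukocyte proteases (18294 against 1903, 9.61-fold lower), and Mmp3, a matrix metalloproteinase (2549 against 269.7, 9.45-fold lower). Sema3e, a secreted guidance protein, was 8.23-fold lower, the prolactin family gene Prl8a1 7.56-fold and Glul, which encodes glutamine synthetase, 6.94-fold. Rgs16, a regulator of G-protein signalling, read below the floor on the array labelled MED1-null and was at least 6.31-fold lower. Bst1 was 6.28-fold lower, Tmem238l 5.73-fold, Gramd1c 5.53-fold, Prune2 5.52-fold and the protease inhibitor gene Serpinb3a 5.50-fold. The probe sets of Rgs16 ran from -2.66 to -0.40 in log2 ratio and those of Prune2 from -2.46 to -0.44. Of the 186 genes beyond 2-fold with several probe sets at the floor, 162 had all of them in the same direction and 24 did not.

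These counts have no replicate check. In a simulated pair of arrays, the spread was taken from the middle of the real ratios at each signal level. There, 155 genes that had not been changed were counted at least 2-fold higher and 128 at least 2-fold lower. That spread also holds any difference between the 2 cultures, so the simulation cannot tell measurement spread from biology. A large part of both counts could still be such general spread. With the floor raised to the 75th percentile of the signal, 434.6, the counts were 49 higher and 106 lower, against 2 and 3 in the simulated pair. The simulated noise was drawn independently for each probe set and array, so 2 and 3 are no measure of what replicate cultures would give. The share of lower genes among those beyond 2-fold was 57.7% and became 65.5%, 66.4% and 69.0% when the arrays were rescaled by the median ratio, by quantiles and by a lowess curve. It was 45.5% with the floor at the 25th percentile (1120 higher and 934 lower) and 46.0% with no floor, so which direction held more genes depended on the floor.

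**Figure D2:**
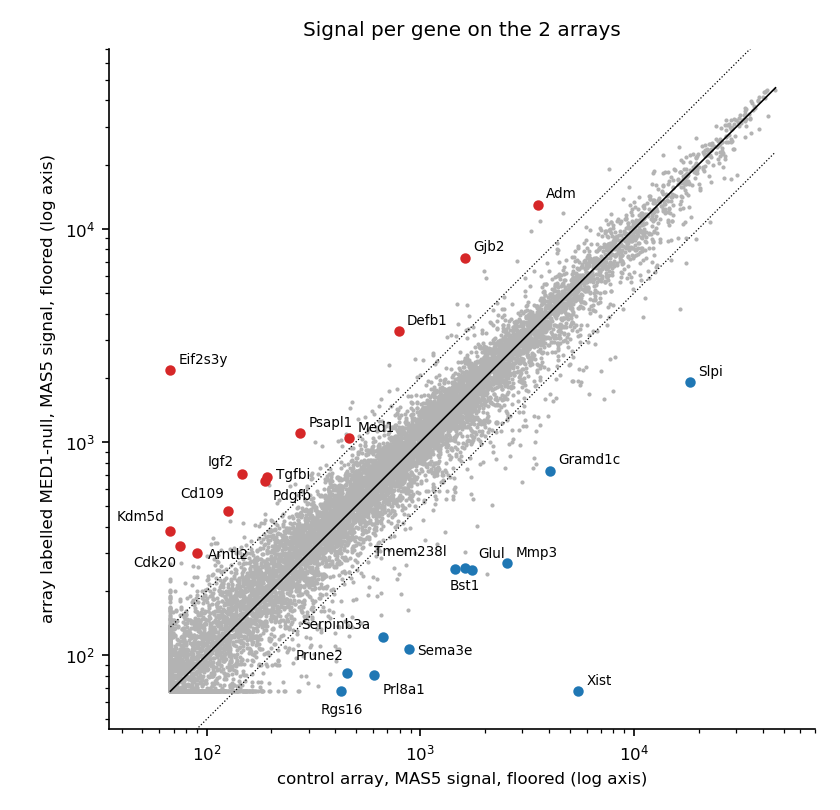
MAS5 signal per gene on the control array (x, log axis) and on the array labelled MED1-null (y, log axis) for genes that reached the floor of 67.7 on either array, with lower values drawn at the floor, the line of equal signal in full and 2-fold lines dotted. Named genes higher on the array labelled MED1-null are red and those lower are blue, and Slpi at 18294 against 1903 and Xist lie farthest below the line.

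Genes of the unfolded protein and amino acid stress response were lower together on the array labelled MED1-null. All 20 members were measured, 8 were at least 2-fold lower, none was higher, and each had a log2 ratio below 0. The median log2 ratio was -0.85 (1.81-fold), below the medians of all 10000 random lists matched on signal, as a description of these 2 arrays. Chac1, which degrades glutathione, read 2979 and 650.2 (4.58-fold lower), and the ATF4 target Trib3 read 1837 and 402.8 (4.56-fold lower). Herpud1, part of endoplasmic reticulum protein degradation, read 3465 and 791.1 (4.38-fold lower), and the stress transcription factor Ddit3 read 3412 and 840.1 (4.06-fold lower). The probe sets of Trib3 ran from -2.19 to -1.95 in log2 ratio and those of Ddit3 from -2.02 to -0.95. Heat shock protein genes did not go the same way: 12 of 13 lay within 2-fold, and Hspb8, a small heat shock protein, was 2.55-fold lower. Hspa8 was 1.49-fold higher and Cryab 1.29-fold lower, with probe sets that went both ways for each, and Hspa1a was 1.25-fold higher. Their median of 0.05 and mean of -0.02 differed in sign, and the median was -0.01 when the median ratio of the arrays was set to 0. Of 19 immediate early genes, the transcription factor Egr2 was 3.10-fold higher and Atf3, which the stress list also holds, lower at 1716 against 685.2. Egr1 was 1.97-fold and Egr3 1.73-fold higher, and the list's median of 0.16 lay at percentile 98 of the random lists.

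**Figure D3:**
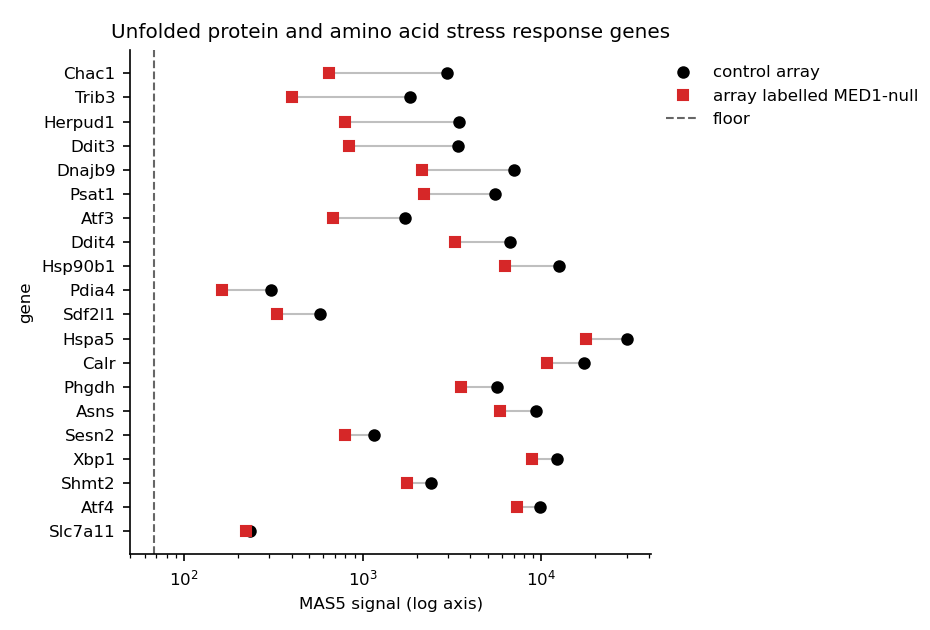
MAS5 signal on a log axis for the 20 genes of the unfolded protein and amino acid stress response, with the control array as circles, the array labelled MED1-null as squares and the floor as a dashed line. Each square lies to the left of its circle, from Chac1 at 2979 against 650.2 down to Slc7a11 at 234.2 against 221.6.

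The medians of epidermal differentiation genes differed in direction by class. Most lipid genes of the skin barrier were lower on the array labelled MED1-null. Of 24 measured ceramide and barrier lipid genes, 17 had a log2 ratio below 0 and 7 above. The median was -0.41 at percentile 0.01. None was at least 2-fold higher, 20 lay within 2-fold and 4 were at least 2-fold lower. The 4 lower genes were Sptlc3, a subunit of serine palmitoyltransferase (838.3 against 304.0, 2.76-fold lower), the lipoxygenase Alox12b (3118 against 1192, 2.61-fold), the ceramide desaturase Degs2 (2.19-fold) and the ceramide synthase Cers3 (8902 against 4180, 2.13-fold). Cornified envelope and late differentiation genes had a median of -0.20, also at percentile 0.01, with members on both sides. It was -0.10 without probe sets whose suffix marks shared sequence, such as the one used for Lce1h. Of 43, the protease gene Klk6 was 2.88-fold higher and the protease inhibitor Cst6 2.35-fold higher, while Cdsn, which encodes the adhesion protein corneodesmosin, was 2.36-fold lower. The late cornified envelope genes Lce1h and Lce1b were 2.35-fold and 2.10-fold lower, and Lce1b was named after its value was seen. Genes of the spinous layer were mostly higher, with 10 of 13 above 0 and 3 below, and a median of 0.37 at percentile 99.9. Calml3, a calmodulin-like protein, was 2.40-fold higher, the desmosomal cadherins Dsg1a and Dsc1 2.24-fold and 1.76-fold, and Krtdap 1.75-fold. By the probe set used, none of the 14 measured basal keratinocyte genes differed 2-fold. Of these, 12 had a log2 ratio above 0, and the median of 0.25 lay at percentile 100 of the random lists. Trp63, the transcription factor p63, read 7798 and 11736, and the hemidesmosome collagen Col17a1 12385 and 18599. The probe sets of Trp63 ran from 0.59 to 1.11 in log2 ratio. With the floor at the 75th percentile of the signal the spinous layer median was 0.06.

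Cell cycle genes were modestly higher on the array labelled MED1-null. None of 27 mitotic genes reached 2-fold, yet 23 had a log2 ratio above 0 and the median was 0.37. Bub1, a spindle checkpoint kinase, was 1.84-fold and the proliferation marker Mki67 1.79-fold higher. Of 25 DNA replication genes, 23 were above 0, with a median of 0.43, and thymidine kinase Tk1 was 2.30-fold higher. Ccne2 and E2f1, which act at entry into S phase, were 1.80-fold and 1.79-fold higher, while the probe sets of Fen1 disagreed, from -0.86 to 0.27. Both medians lay at percentile 100 of the random lists after rounding. The 20 measured CDK inhibitor and p53 target genes lay within 2-fold, with a median of 0.10 at percentile 80.1, Btg2 at 1.74-fold higher and Bbc3 at 1.58-fold lower.

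Of 13 stress keratin and alarmin genes, 5 were at least 2-fold lower on the array labelled MED1-null: Slpi, the calprotectin subunit genes S100a8 (16313 against 4185, 3.90-fold) and S100a9 (7669 against 2446, 3.14-fold), the beta-defensin Defb3 (2.42-fold) and Lcn2 (at least 2.47-fold). Defb3 and Lcn2 were named after their values were seen. S100a3 was 3.30-fold higher. The list's median of 0.05 lay at percentile 65, the mean was -0.49, and the median turned below 0 under all 3 rescalings of the arrays. Inflammatory mediators went both ways, with 5 of 28 at least 2-fold higher and 4 lower and a median of 0.10 at percentile 77.4. The alarmin cytokine Il33 was 3.20-fold higher and Saa3 2.83-fold higher, while the granulocyte growth factor Csf3 was 3.14-fold lower and the decoy receptor Il1r2 3.02-fold lower. Icam1 (2.51-fold), Tnfaip3 (2.31-fold) and Ccl27a (at least 2.45-fold) on the higher side, and Il1a (2.27-fold) and Csf2 (at least 2.10-fold) on the lower side, were named after their values were seen. Il1a read 6524 and 2871. Of 15 interferon and antigen presentation genes, Xaf1 was 2.02-fold higher and Irf7 at least 2.49-fold lower, Ifih1 1.72-fold and Oas1a 1.49-fold higher, and the median of 0.06 at percentile 45.8 turned below 0 under all 3 rescalings.

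Genes of migration, matrix and proteolysis included 5 of 24 that were at least 2-fold lower on the array labelled MED1-null. After Mmp3 came the metalloproteinase Adam12 (3.34-fold lower), the intermediate filament gene Vim (2602 against 979.7, 2.66-fold), fibronectin Fn1 (2.41-fold) and Mmp2 (2.08-fold). The integrin gene Itgb6 was 2.03-fold higher, and it and Mmp2 were named after their values were seen. The list's median of 0.12 at percentile 92.0 and its mean of -0.17 differed in sign. Markers of some other cell types were lower as well. Fibroblast markers had a median of -0.50 at percentile 0.02 over 14 genes, and Sparc, a matrix-binding protein, read 2709 and 1034 (2.62-fold lower), while Col3a1, Dcn and Twist2 read 120.8, 118.1 and 112.9 on the control array and below the floor on the other. Melanocyte markers had a median of -0.23 at percentile 1.04 over 12 genes, with Gpnmb 3.09-fold and the receptor Kit 2.99-fold lower, and the pigment genes Tyrp1 and Mlana each 1.39-fold lower. Both pigment genes read far above the floor on both arrays, Tyrp1 at 9346 and 6715 and Mlana at 2258 and 1629. Melanocyte transcripts were thus present in both cultures. The 2 probe sets of Gpnmb differed in size, with log2 ratios of -1.63 and -0.16.

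Among signalling lists, that of EGF receptor signalling stood highest among its random lists. The 19 measured EGF receptor ligands and feedback genes had a median of 0.28 at percentile 99.7 and a mean of 0.13. The phosphatase Dusp6 was 1.68-fold and the transcription factor Etv4 1.54-fold higher, while Dusp4 was 2.29-fold and Etv5 1.53-fold lower. Of 22 TGF-beta, activin and BMP genes, Tgfbi, the matricellular Ccn1 (2830 against 7077) and the activin antagonist Fst (7632 against 19025, 2.49-fold) were higher. The activin subunit gene Inhbb was 2.77-fold lower, and the list's median was 0.17 at percentile 94.1, and 0.11, 0.06 and 0.05 under the 3 rescalings. Of 27 Wnt genes, Wnt5a was 4.66-fold lower and Wnt10a 2.43-fold higher. Fzd8, a Wnt receptor, was at least 1.95-fold and cyclin D1, Ccnd1, 1.60-fold higher, and the median was -0.02 at percentile 15.1, and -0.10, -0.08 and -0.09 under the rescalings. Of 15 Notch genes, the receptor Notch1 (773.8 against 1779, 2.30-fold) and its modifier Lfng (2.11-fold) were higher, as were Notch3 (1.47-fold) and the target gene Hes1 (1.36-fold). The Notch median of 0.02 at percentile 31.6 became -0.05 when the median ratio of the arrays was set to 0. Of 8 Hedgehog genes, the coreceptor Cdon was 3.17-fold, the receptor Ptch1 1.37-fold, Sufu, whose probe sets disagreed, 1.21-fold and Gli2 1.17-fold higher, with a median of 0.12 at percentile 56.1 that was 0.06, 0.03 and 0.01 under the rescalings.

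MED1 was first described as a coactivator of nuclear receptors, and lists of these receptors and their targets were examined. Of 19 nuclear receptors and coregulators, Nr1d2, a heme-binding repressor of the circadian clock, was 2.01-fold lower and its paralog Nr1d1 1.85-fold lower. The coactivators Ncoa2 and Ncoa1 were 1.80-fold and 1.64-fold lower, and the list's median was -0.05 at percentile 11.7. That median moved with the processing, to -0.17, -0.16 and -0.18 under the 3 rescalings and -0.38 with no floor, and the mean was -0.23. Its highest value over all alternatives was -0.001. Of 8 vitamin D and retinoid genes, the retinoic acid hydroxylase Cyp26b1 was 2.37-fold and Cst6 2.35-fold higher, and the binding protein Crabp1 3.45-fold lower, while Crabp2 was 1.22-fold higher, with a median of 0.23 at percentile 94.2. Of 16 PPAR target genes, the lipoprotein lipase inhibitor Angptl4 was 2.18-fold, Acaa2 1.55-fold and Cpt2, whose probe sets disagreed, 1.43-fold higher and Creb3l3 1.38-fold lower, with a median of 0.07 at percentile 57.4. The 20 cholesterol synthesis genes lay within 2-fold, and had a median of -0.07 at percentile 16.0, Stard4 being 1.33-fold higher and Cyp51, whose probe sets disagreed, 1.28-fold lower. Of 11 sebocyte and lipid storage genes, Scd3 was at least 2.27-fold, Plin5 1.47-fold and Scd2 1.26-fold lower and Acsbg1 1.33-fold higher, with a median of -0.08 at percentile 17.6. Under the 3 rescalings the vitamin D and retinoid median was 0.17, 0.16 and 0.14, and that of PPAR targets 0.01, 0.06 and 0.03. The cholesterol median was then -0.13, -0.05 and -0.07, and the sebocyte median -0.15, -0.11 and -0.10. Of 15 hair follicle stem cell genes, Runx1 was 2.42-fold higher, with probe sets that went both ways, Sox9 1.71-fold higher, Lhx2 at least 2.69-fold lower and Tbx1 1.99-fold lower, with a median of -0.11 at percentile 7.65. It was -0.17, -0.19 and -0.21 under the rescalings and 0.15 with the floor at the 75th percentile. Of 12 hair shaft and inner root sheath genes, Krt75 was 3.24-fold higher, Padi3 at least 2.21-fold, Krt83 at least 1.97-fold and Krt36 1.65-fold lower. That list's median was -0.34 at percentile 0.25 and became 0.40 with the floor at the 75th percentile.

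Lists of general cell function held few genes beyond 2-fold. Of 22 hypoxia and glycolysis genes, Adm was 3.68-fold and Egln1 1.54-fold higher, while Vegfa was 1.84-fold and Ndrg1 1.60-fold lower, with a median of 0.15 at percentile 96.8. Of 24 antioxidant and NRF2 target genes, Gsta2 was at least 2.97-fold and Gsta3 at least 1.58-fold higher, and Txnip and the thioredoxin reductase Txnrd1 (19546 against 8957) were 2.56-fold and 2.18-fold lower, with a median of -0.06 at percentile 11.2. The 33 oxidative phosphorylation genes lay within 2-fold, Sdhd, whose probe sets disagreed, and Ndufs1 being 1.25-fold and 1.22-fold higher, with a median of 0.03 at percentile 81.3. Of 24 ribosomal protein genes, Rps27 was 2.11-fold, Rpl14 1.18-fold and Rps4x 1.10-fold higher and Rpl37 1.27-fold lower, with a median of 0.03 at percentile 76.1. The 12 reference genes lay within 2-fold, Ywhaz, whose probe sets disagreed, 1.26-fold lower and Polr2a 1.25-fold higher, with a median of -0.03 at percentile 31.8 and a mean of 0.01. The sign of the medians of these last 3 lists turned under at least 1 rescaling of the arrays.

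Further cell type markers were mostly near or below the floor. Of 8 measured Langerhans cell, dendritic cell and macrophage markers none differed 2-fold (median 0.23, percentile 94.4), nor did any of 5 Schwann cell markers (-0.30, percentile 3.52) or 7 simple epithelium markers. This holds for the probe set of highest signal: those of the Schwann cell marker Mbp ran from -1.51 to -0.63 in log2 ratio. The median of the simple epithelium markers, 0.01 at percentile 37.6, turned below 0 under 2 of the 3 rescalings. Fewer than 5 members were measured in the other marker lists. Zap70, 3.54-fold higher, was the only 1 of 7 T cell markers on the array that was measured. The endothelial Flt1 was at least 2.75-fold higher, with probe sets from 0.12 to 1.46 in log2 ratio. Of the 4 measured endothelial markers, 2 had a log2 ratio above 0 and 2 below. The smooth muscle Tagln was 2.81-fold lower. The mast cell list was represented by Kit and Tpsb2, with a median of -0.75. Medians were 0.24 over 4 endothelial, -0.11 over 3 Merkel cell, -0.56 over 3 smooth muscle, 0.32 over 3 skeletal muscle and 0.44 over 3 adipocyte markers, and 0 erythroid markers were measured.

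**Figure D4:**
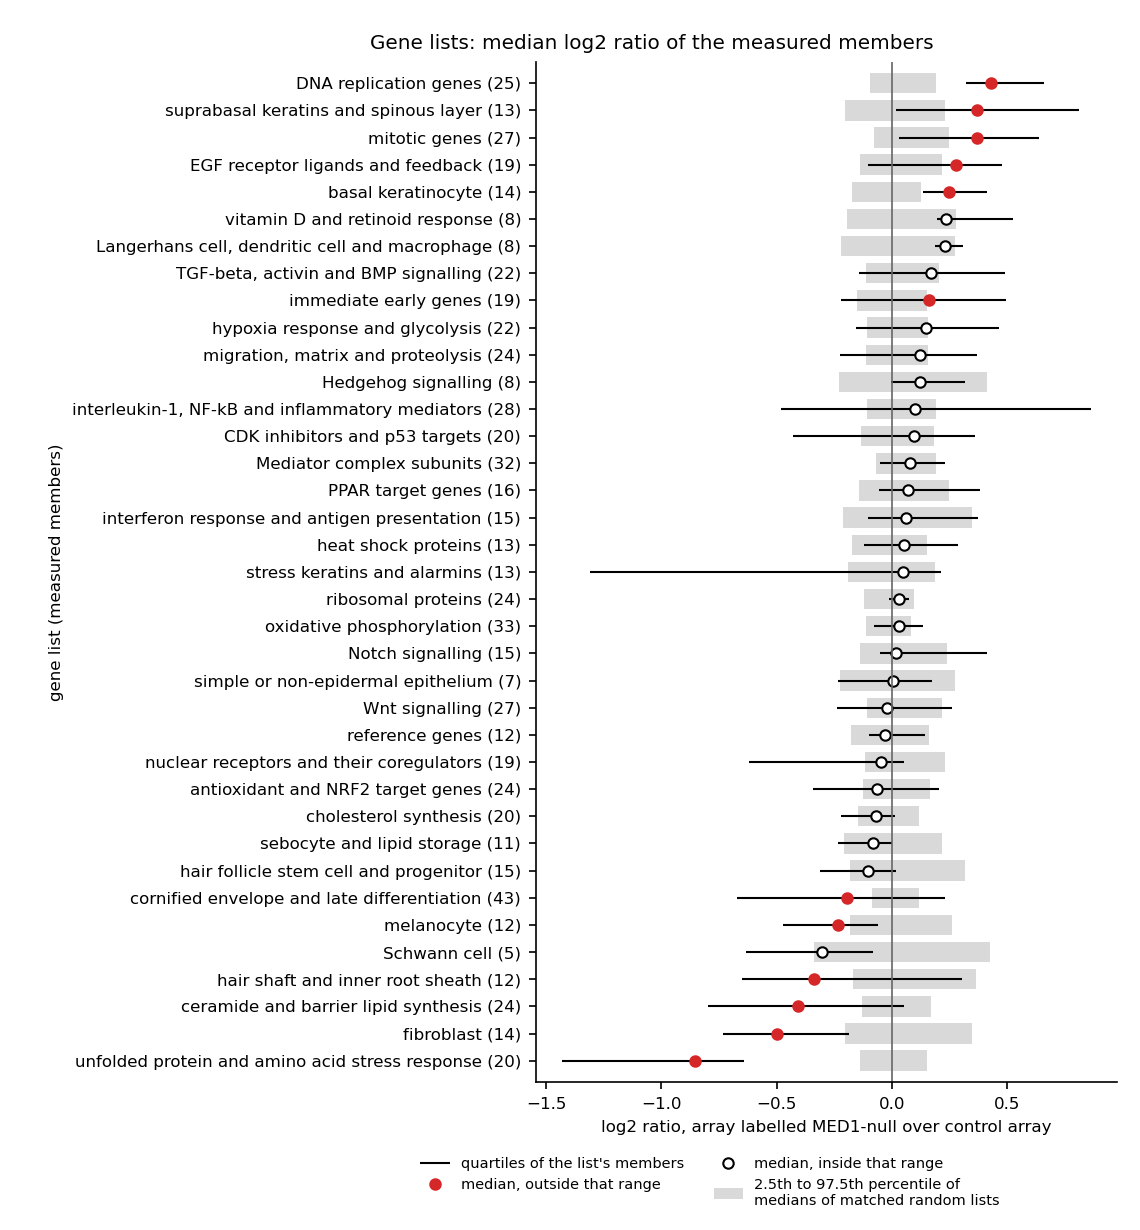
Median log2 ratio (array labelled MED1-null over control array) of each gene list with at least 5 measured members, with the quartiles of the members as lines and the central range of the medians of matched random lists as grey bars. Of 37 lists, 6 medians lie below and 6 above their grey bar (red), with the stress response list lowest at -0.85 and the DNA replication list highest at 0.43.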

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

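The tests of the other Mediator subunits, of exchanged labels, of fibroblasts and of melanocytes were chosen only after the results they concern had been seen.

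A control probe set for the 5′ end of 18S ribosomal RNA, which no comparison above uses, read 1273 on the control array and 22807 on the array labelled MED1-null, 17.92-fold higher. It stood out as a signal outside the main measurement that exceeded the control array. The probe set for the middle of the same RNA read 780.5 and 1330, and that for its 3′ end 710.0 and 659.1.

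Med1, the gene the label says was deleted, was higher on the array labelled MED1-null. Array scaling is argued against, because the whole-array offset was small, with a median log2 ratio of 0.06. Under 3 rescalings the log2 ratio of Med1 stayed at 1.096 or more, above the probe set SD of 0.31. The 3 other floors could not bear on it, because both signals of the probe set used, 462.7 and 1039, lie above the highest, 434.6. A shift shared by Mediator subunit genes is argued against by the median of the other measured subunits, 0.053. Exchanged labels and a truncated Med1 transcript with a higher level in the MED1-null culture cannot be told apart: 7 of 7 probe sets were higher, and none could be placed inside the deleted part. Neither was shown, and they are not the only possible causes. The sex of the cells and the state of each culture cannot be told apart from them with 1 array per group. Xist and the Y-linked genes show that the arrays came from cultures of different sex composition, but no label gives the sex of either, so they do not settle which array is which.

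The stress response list was lower on the array labelled MED1-null, with a median of -0.85. Scaling or a signal-dependent bias is argued against, because the median was -0.916, -0.909 and -0.933 under the 3 rescalings. With an array-wide median log2 ratio of 0.06, rescaling had little room to move it. The highest median with the other floors was -0.853. A lower amino acid response may be part of it: 12 tRNA synthetase genes known as ATF4 targets, none of them in the list, were all below 0 with a median of -0.555, at percentile 0.01 of matched random lists, while 7 other cytosolic synthetases had a median of -0.05. A lower endoplasmic reticulum chaperone response may be another part, as 13 chaperone and degradation genes outside the list had a median of -0.379, below all 10000 random lists, with 11 of them below 0. Whether this goes with the genotype, the sex of the cells or the state of each culture was not tested and cannot be with 1 array per group.

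The fibroblast marker list was lower on the array labelled MED1-null, with a median of -0.50 over 14 measured genes, 12 of them below 0. Scaling is argued against, because the highest fibroblast median under the rescalings and floors was -0.532. Fewer fibroblasts in the culture stay open and cannot be told apart from lower levels within the same cells: of the collagens Col1a1, Col1a2 and Col3a1, 0 of 3 reached 4 times the floor on the control array, so they lie too near the floor to decide. Col1a2 was 1.44-fold higher on the array labelled MED1-null, at 80.3 and 115.3, and Col1a1 was below the floor on both arrays. Col3a1, Dcn, Twist2, Col5a2, Loxl1 and Thy1 read above the floor on the control array and below it on the other. Fewer melanocytes stay open as well: the 7 pigment genes had a median of -0.263, neither far enough below 0 nor far enough from the fibroblast marker median to decide. Gpnmb and Kit were 3.09-fold and 2.99-fold lower, though the other Gpnmb probe set had a log2 ratio of -0.16. A lower level of these genes within keratinocytes stays open as a hypothesis, untested, as do the sex of the cells and the state of each culture.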

How the results depend on the processing

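The alternatives that leave out X and Y genes or the stress response genes were chosen after seeing the data. Leaving out single arrays was not possible with 1 array per group. Med1 kept its direction under all 8 alternatives, with log2 ratios from 1.10 to 1.17. Counts of genes at least 2-fold higher and lower depended most on the floor: 1120 and 934 at the 25th percentile, 2229 and 1901 with no floor, and 49 and 106 at the 75th percentile, against 190 and 259. A lower floor admits dim probe sets whose ratios are noisier, and the share of lower genes was 45.5% and 46.0%. At 1.5-fold the counts were 906 and 851, at 3-fold 28 and 73, and over probe sets in place of genes 455 and 470, each by construction. The other 7 alternatives gave 140 to 183 higher and 210 to 312 lower, and without X and Y genes the counts were 183 and 251. The probe set SD was 0.21 at the 75th percentile floor. Most alternative list medians moved by less than 0.31. Among lists with at least 5 measured members and a median outside the random range, 1 turned its sign: hair shaft and inner root sheath genes, -0.34, became 0.3968 at the 75th percentile floor, where 2 of the 12 members measured otherwise reached the floor. Smaller lists outside the range turned too, as members dropped out. The X-inactivation and Y-linked median went from 2.10 to -0.67 at the 75th percentile floor. There Kdm5d (380.9) and Uty (221.7) no longer reached the floor, while Xist stayed lower and Eif2s3y higher on the array labelled MED1-null. The mast cell median went from -0.75 to 0.09 without probe sets whose suffix marks shared sequence. That value equals the log2 ratio of Tpsb2 alone, so neither turn shows a gene that changed direction. Lists with a median inside the range that changed sign under at least 1 alternative were those of alarmins, interferon, migration, Wnt, Notch, hair follicle stem cells, heat shock, antioxidant, oxidative phosphorylation, ribosomal and reference genes, and Langerhans cell, endothelial, adipocyte and simple epithelium markers. The stress response median ran from -1.07 to -0.85. Of the alternative values of named genes, 1123 moved by less than the probe set SD and 89 by more. The floor is the median of both arrays pooled, so the 49.0% and 51.0% of probe sets that reached it follow from its definition. Ratios against the floor are bounds, which limits what can be read from dim genes.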

Other observations

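The gene families in this part were chosen after their values were seen, and no list of them was fixed beforehand. Of 6 measured connexin genes, Gjb2 (1617 against 7311) and Gjb6 (1488 against 4445, 2.99-fold), the connexins 26 and 30 mutated in inherited skin and hearing disorders, were at least 2-fold higher on the array labelled MED1-null. Gjb5 was 1.89-fold higher, while Gja1 read 10386 and 10731, and Gja4 and Gjc1 had log2 ratios of -0.11 and -0.01. The epithelial sodium channel went the other way: its subunit genes Scnn1b (774.5 against 226.3, 3.42-fold) and Scnn1g (1423 against 541.3, 2.63-fold) were lower, and Scnn1a was 1.55-fold lower. Of 4 measured prolactin family genes, which are known mostly from the placenta, Prl8a1, Prl8a9 (1196 against 330.8) and Prl7b1 (276.0 against 79.8) were at least 2-fold lower. Members of this family share sequence, so their probe sets may not be independent. Leaving out probe sets whose suffix marks shared sequence gave 170 higher and 210 lower genes over the whole arrays, and overlap within this family was not tested.

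Several imprinted genes lay far from the line of equal signal, in both directions. Of 15 measured, Igf2 and Mest (446.8 against 1088, 2.44-fold) were at least 2-fold higher on the array labelled MED1-null, and Peg3 (2253 against 829.2, 2.72-fold) and Plagl1 (5109 against 1932, 2.64-fold) at least 2-fold lower, with 3 and 2 probe sets in the same direction. The median over the 15 was -0.09. Of 13 measured genes of alcohol and retinal metabolism, 4 were at least 2-fold higher, 1 lower and 8 within 2-fold: Adh1 was at least 3.97-fold, Adh6b at least 3.36-fold, Sdr16c5 2.53-fold and Rdh9 2.41-fold higher, while Aldh1a3, which makes retinoic acid, was lower at 5474 against 1931. Of 9 amino acid transporters of the Slc7 family, Slc7a3 (811.6 against 193.8, 4.19-fold) and Slc7a5 (1448 against 579.3) were lower. Of 16 clock genes, Arntl2 was higher and Nr1d2 lower by at least 2-fold, Nr1d1 and Ciart were 1.85-fold and 1.83-fold lower, and Clock read 1043 and 1009. These directions held under the 3 rescalings of the arrays for each gene named here except Gja1, whose log2 ratio of 0.05 became -0.02 when the median ratio was set to 0. Clock was lower under all 3. The probe sets of Gja1 and of Clock disagreed in direction.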
